A study of Arabidopsis thaliana with 19 samples.

How the data were processed

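The samples were sperm nuclei of Arabidopsis thaliana ecotype Col-0, sorted from a line with an HTR10-Clover reporter, with chromatin digested to mononucleosomes by micrococcal nuclease. There were 19 samples: 3 immunoprecipitations each of H3K4me3, H3K27ac and H3.10, 2 each of H3K27me1 and H3K27me3, and 2 sets of 3 inputs. By the replicate descriptions, the immunoprecipitations of the 4 marks came from the same set of 3 input chromatin preparations, and those of H3.10 from the other set. The processing notes name Trim Galore 0.4.1, Bowtie2 2.1.0, SAMtools 1.3, Picard, bedtools, deepTools 2.5.0.1 and MACS2 2.1.0 with the genome build TAIR10. The settings and the role of each tool are not given in the sources used here.

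The values used were 8 deposited peak lists, a narrow and a broad list for each of H3K4me3, H3K27ac, H3K27me1 and H3K27me3. Each deposited list gives peak coordinates on TAIR10, and the narrow lists also give the summit offset in bp. For each peak the authors give a fold, the ratio of the immunoprecipitation to the control expected by the peak caller. The authors also give a significance per peak as −log10 q, a transformed q value on the −log10 p scale. The fold of broad peaks did not follow that of the narrow peaks within them for any mark, so whether fold and q in the broad lists belong to the coordinates of their peak is open. The coordinates themselves do not depend on it. Each list covers all replicates of its mark, so there are no values per sample, no depth per sample and no replicate error, and intervals given here describe counts of genes or peaks only. No peak list of H3.10 and no input signal was used here.

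Peak starts were turned from counts from 0 to counts from 1. Genes came from a table of the assembly TAIR10.1, without strand, sequence or a separate class of transposable elements. The chromosomes of both assemblies were checked for a common frame by shifting the H3K4me3 summits against gene ends by up to 5000 bp in steps of 250 bp. In all 59 segments of 2 Mb with at least 50 summits the best offset was 0 bp. Gene coordinates are not given for that reason, and peak coordinates are those of the authors. Pericentromeres were runs of 500 kb windows with low protein-coding gene density (chromosome 1, 13 to 17 Mb; 2, 2 to 7 Mb; 3, 11 to 16 Mb; 4, 3 to 6 Mb; 5, 10 to 14.5 Mb).

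The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The narrow lists of H3K4me3 and H3K27ac and the broad lists of H3K27me1 and H3K27me3 were the main lists. A protein-coding gene was marked when at least 150 bp of its span lay under peaks, over 27444 nuclear genes. Shares of bases per feature and shared bases of marks were compared with 999 random circular shifts along each chromosome, two-sided, for which the smallest p is 0.002. Apart from pericentromeres, each base was given to 1 feature class only, taken in order. The order was within 500 bp of a protein-coding gene end, gene interior, pseudogene or transposon gene, RNA gene, and no annotated gene. Later classes thus hold only the bases outside the earlier ones. Genes with 2 marks and members of gene lists were compared by Fisher's exact test, two-sided, with gene-length strata (Cochran-Mantel-Haenszel, 5 strata) as an alternative. Fold enrichments of genes with both marks were related across genes by Spearman's rho, and by Pearson's r on log2 values, with 100000 permutations. Adjusted p-values are Benjamini-Hochberg values over 24 feature tests, 6 pairs and 52 list tests, with a threshold of 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

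The 13 gene lists were male germline, pollen vegetative cell, Polycomb and H3K27 enzymes, seed and embryo, meristem homeobox and PLETHORA, flower, epidermis with root hair and trichome, imprinted, auxin YUC and PIN, DNA methylation and silencing, histones, photosynthesis, and housekeeping. They held 261 members with repeats, of which 260 were kept. For 28 of these the symbol was not in the gene table and the gene identifier was used. The 1 member left out (ADM) had a symbol that the gene table gives to another gene. Genes were named when they were among the list members with H3K27me3 of highest fold (up to 30), the 8 genes of highest fold per mark, genes under the 5 widest H3K27me3 peaks, or members of the male germline and Polycomb lists. Other genes named, and genes ranked by narrow-list fold, were chosen after their values were seen.

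Calls on simulated data were made at an unadjusted p under 0.05, so their rates do not carry over to the adjusted calls. With simulated peaks placed uniformly, 2 of 100 pairs of independent peak lists were called, and 41 of 1000 random lists of 20 genes. Overlap made by placing 20% of peaks on the other mark was called in 20 of 20 runs, lists with 30% of members marked in 192 of 200, and a correlation of 0.3 over 1000 genes in 100 of 100. Alternatives were the other peak list of each mark, narrow lists for all marks, stricter thresholds (−log10 q of at least 5 or fold of at least 2), merging of peaks within 300 bp, uniform placement, shifts within arms, an overlap of at least 1 bp or of 50% of the shorter peak, windows of 500 bp around either gene end, gene-length strata, the mean fold per gene, genes outside pericentromeres, and the male germline list without HTR10. Sequence motifs and GC content were not analysed because no genome sequence was used here, and windows around gene starts were replaced by windows around either gene end because the table gives no strand.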

Results

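Chromatin of Arabidopsis thaliana sperm was mapped by ChIP-seq for 4 histone H3 marks and for H3.10, the histone H3 variant of sperm. H3K4me3 and H3K27ac are found at transcribed genes, H3K27me3 is the mark laid down by Polycomb repressive complex 2, and H3K27me1 is a mark of heterochromatin. The nuclei were sorted by fluorescence from a line that carries H3.10 fused to the fluorescent protein Clover under the promoter of its own gene HTR10 (MGH3), and mononucleosomes were released with micrococcal nuclease. There were 19 samples. H3K4me3, H3K27ac and H3.10 had 3 immunoprecipitations each, H3K27me1 and H3K27me3 had 2 each, and 2 sets of 3 input samples served as controls. The series title names reprogramming of H3K27me3 in paternal chromatin, and the question addressed here was where each mark lay in sperm and which genes carried it. Each peak list covered all replicates of its mark, so no value has a replicate error and no replicate test was possible. The depth of the samples is unknown from these lists. H3.10 was not analysed here.

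In the lists chosen for each mark, narrow for H3K4me3 and H3K27ac and broad for H3K27me1 and H3K27me3, H3K4me3 covered the most of the sperm genome and H3K27me3 the least. The 22150 peaks of H3K4me3 covered 21.8 Mb, or 18.3% of the 119.144 Mb of the 5 nuclear chromosomes up to their last gene or peak. The 19545 peaks of H3K27ac covered 10.1%, and the 2433 peaks of H3K27me1 covered 5.06%. H3K27me3 had 1423 peaks over 1.44 Mb, which is 1.21% of the same span, so that H3K4me3 covered 15.2 times as many bases, and 60.6 times as many with narrow lists for both. The marks were called at unlike enrichment. In the narrow lists the median fold was 4.55 for H3K27me3, with a median −log10 q of 5.35. The median fold was 1.74 for H3K27ac with 7.15, and 3.70 for H3K4me3 with 65.3. H3K27me3 of low fold may thus be missing, so these shares describe called peaks and not amounts of each mark. Median peak widths were 841 bp for H3K4me3 and 519 bp for H3K27ac in the narrow lists, and 1353 bp for H3K27me1 (quartiles 740 and 2698 bp) and 731 bp for H3K27me3 in the broad lists, where H3K4me3 had 1443 bp. The narrow H3K27me1 list held 13130 peaks over 24.5 Mb (20.6% of the span), more than H3K4me3, the narrow H3K27me3 list 478 peaks over 0.302%, and the broad H3K27ac list 163 peaks. The broad H3K27me3 list gives a q value over 0.05 for 1047 of its 1423 peaks (73.6%). For none of the 4 marks did the folds in the broad list follow those of the narrow peaks they contain (rho −0.0562 for H3K4me3, −0.00629 for H3K27ac, −0.151 for H3K27me1 and −0.0468 for H3K27me3), so whether the fold and q of a broad peak belong to its coordinates is open, and every broad fold or q given here carries that limit.

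**Figure D1:**
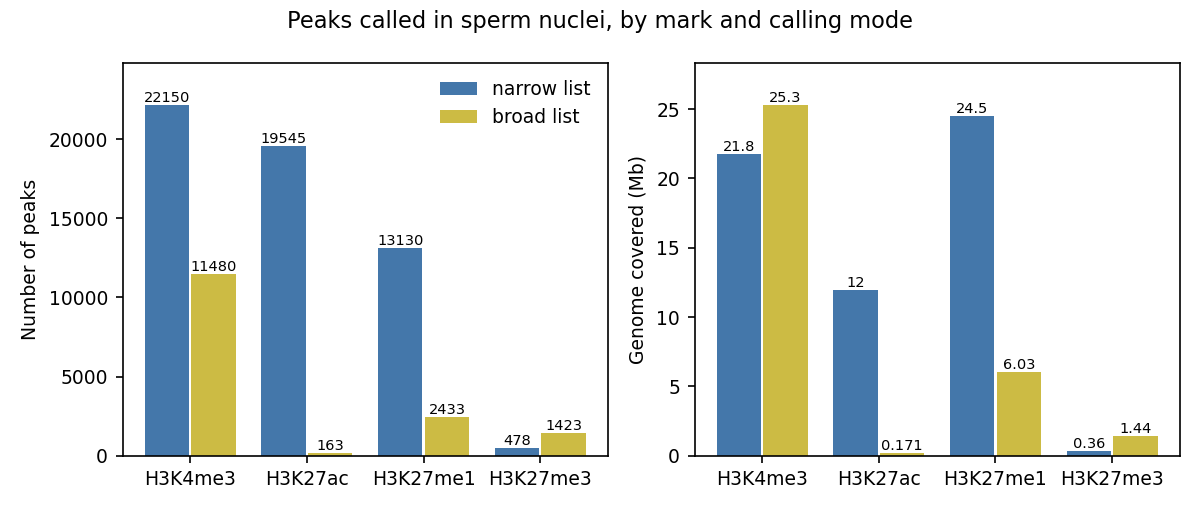
Number of peaks (left) and bases covered in Mb (right) for each mark, with a bar for the narrow and for the broad peak list. H3K4me3 has the most narrow peaks (22150), and H3K27me3 covers 1.44 Mb in the broad and 0.360 Mb in the narrow list.

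H3K4me3 and H3K27ac were concentrated on the gene-rich arms, and H3K27me1 was higher in the pericentromeres. The pericentromeres, defined by low gene density, made up 18.0% of the span and held 2.99% of the H3K4me3 bases and 2.18% of the H3K27ac bases, against 17.9% in randomly shifted lists for each. H3K27me1 had 24.9% of its bases there against 17.5% in shifted lists (ratio 1.43, adjusted permutation p = 0.048). H3K27me3 had 17.8% of its bases there against 18.2% in shifted lists (ratio 0.977, adjusted permutation p = 0.914). Pseudogenes and transposon genes were not separated by the annotation and were counted outside protein-coding genes and the 500 bp around their ends. They held 12.9% of the H3K27me1 bases, 1.57 times the shifted value. The ratio was 0.213 for H3K4me3, 0.160 for H3K27ac and 0.447 for H3K27me3. Each of these 4 ratios had a permutation p of 0.002, the smallest the random shifts can give, and an adjusted p of 0.0032 over 24 tests. In the narrow list, 53.0% of the H3K27me1 bases lay in pericentromeres, a ratio of 2.83, and 28.9% in pseudogenes and transposon genes, a ratio of 3.30, while for H3K27me3 the latter ratio was 0.252. The broad H3K27me1 list leaves out much of this pericentromeric signal. On chromosome 4 from 4000001 to 4500000 it covered 0% and the narrow list 78.4%. On chromosome 1 from 15500001 to 16000000 these were 31.2% and 72.2%. With H3K27me1 peaks of −log10 q of at least 5 the ratio was 0.761 in pericentromeres and 0.759 in pseudogenes and transposon genes, a selection by the broad-list q, whose link to the coordinates is open.

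**Figure D2:**
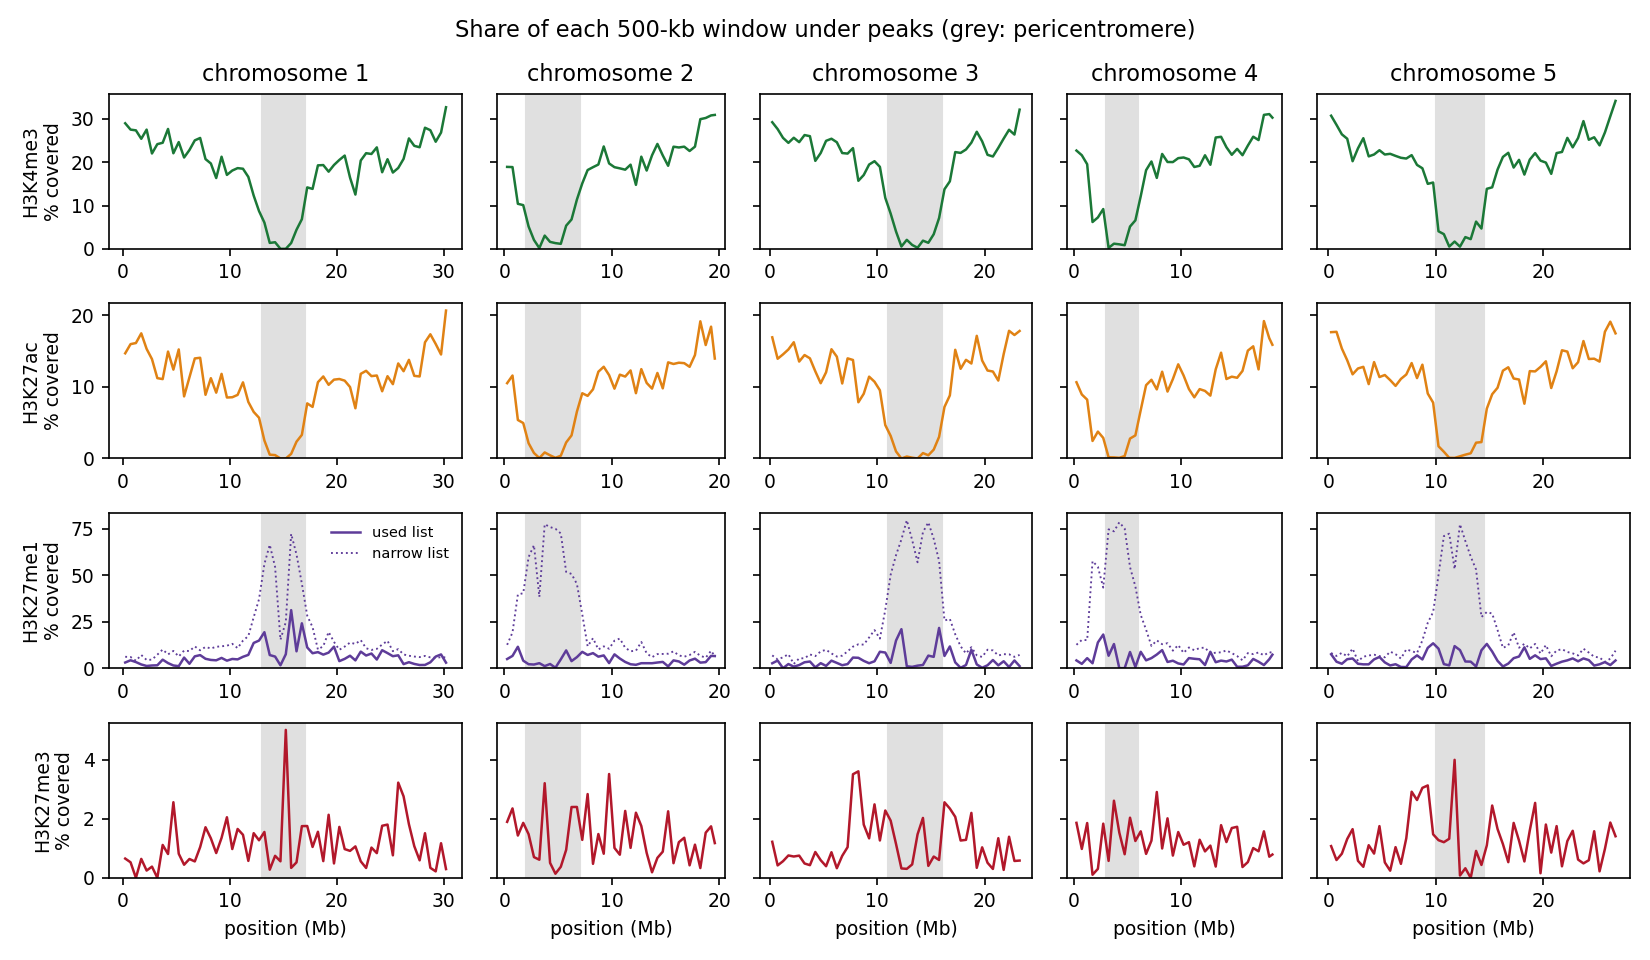
Percent of each 500 kb window under peaks of each mark along the 5 chromosomes, with position in Mb, pericentromeres shaded and the narrow H3K27me1 list dotted. H3K4me3 and H3K27ac drop in the shaded regions, which hold 2.99% and 2.18% of their bases.

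Along genes, the active marks lay near the ends and the other marks further from them. Regions within 500 bp of either end of a protein-coding gene held 53.4% of the H3K4me3 bases and 54.1% of the H3K27ac bases, 1.51 and 1.53 times the shifted values (adjusted permutation p = 0.0032 for each). H3K27me1 was lower there at 28.4% (ratio 0.802, adjusted permutation p = 0.0032), and H3K27me3 stood at the shifted value (35.3%, ratio 1.00, adjusted p = 0.964). The interior of genes held 35.5% of the H3K27me3 bases against 32.0% in shifted lists (ratio 1.11, adjusted permutation p = 0.0169), and 48.1% in the narrow list (ratio 1.50). H3K4me3 was also higher in gene interiors (39.3%, ratio 1.22, adjusted permutation p = 0.0032), whereas H3K27ac (ratio 1.09, adjusted p = 0.0783) and H3K27me1 (ratio 0.917, adjusted p = 0.101) did not pass the test. RNA genes were counted only where they lay outside protein-coding genes, the 500 bp around their ends and pseudogenes. There they carried more H3K4me3 (ratio 1.198), H3K27ac (ratio 1.57) and H3K27me3 (ratio 1.65, adjusted permutation p = 0.0169) than shifted lists, and H3K27me1 did not pass (ratio 1.19, adjusted p = 0.167). Sequence with no annotated gene held little H3K4me3 (4.46%, ratio 0.192) or H3K27ac (8.05%, ratio 0.347), more H3K27me1 (28.1%, ratio 1.21), and H3K27me3 near the shifted value (23.8%, ratio 1.02, adjusted permutation p = 0.729). With the other peak list of each mark, that last ratio was 0.665 for H3K27me3, and H3K27me1 was lower in gene interiors (ratio 0.602) and at gene ends (ratio 0.464). In those lists the ratios at RNA genes no longer passed for H3K4me3 (ratio 1.06), H3K27ac (ratio 1.23) and H3K27me3 (ratio 1.59), as did those of H3K4me3 in gene interiors (ratio 1.11, adjusted permutation p = 0.051) and of H3K27ac in sequence with no annotated gene (ratio 0.723). Summits of H3K4me3 had a median distance of 370 bp to the nearest end of a protein-coding gene and those of H3K27ac 375 bp, against 812 bp for the middles of H3K27me1 peaks and 723 bp for those of H3K27me3 peaks.

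Most protein-coding genes lay under called H3K4me3 peaks and few under called H3K27me3 peaks, a difference limited by the unlike calling of the marks. Of 27444 nuclear protein-coding genes, 20642 (75.2%) had at least 150 bp under H3K4me3 peaks, 15345 (55.9%) under H3K27ac, 2412 (8.79%) under H3K27me1 and 1105 (4.03%) under H3K27me3. H3K4me3 and H3K27ac without the other marks were the most frequent combination, with 13190 genes (48.1%), followed by no mark (5243 genes, 19.1%) and H3K4me3 alone (5085 genes, 18.5%). H3K27me3 was the only mark on 174 genes, and 540 genes had it beside H3K4me3 and H3K27ac. In the narrow lists, 405 genes (1.48%) carried H3K27me3 and 7370 genes (26.9%) carried H3K27me1.

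The marks were then compared in pairs, to see which occurred together. H3K27ac lay mostly at H3K4me3. The pair shared 9983 kb against 2198 kb in shifted lists (ratio 4.54), and 85.4% of H3K27ac peaks touched an H3K4me3 peak. H3K27me3 also overlapped H3K4me3, with 572 kb shared against 262 kb (ratio 2.18), and 836 of its 1423 peaks (58.7%) touched an H3K4me3 peak. The ratio was 1.96 for H3K27me3 with H3K27ac and 1.83 for H3K27me3 with H3K27me1. H3K27me1 overlapped H3K27ac less than shifted lists did (ratio 0.732), and its overlap with H3K4me3 did not pass the test (ratio 0.934, permutation p = 0.284), though it was lower in the narrow lists (ratio 0.612) and with the other list of both marks (0.510), and higher with −log10 q of at least 5 (1.26). The other 5 pairs had p = 0.002, the smallest the shifts can give, and adjusted permutation p = 0.0024 over the 6 pairs. The immunoprecipitations shared input samples, so the lists are not independent of each other. With the other list of both marks, the narrow one of H3K27me3 and the broad one of H3K27ac with its 163 peaks, their ratio was 0.798.

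Counted by gene, 14691 of the 15345 genes with H3K27ac (95.7%) also had H3K4me3 (odds ratio 23.2, 95% interval 21.3 to 25.3). H3K4me3 was less frequent on genes with H3K27me1 (66.0% against 75.2% of all genes, odds ratio 0.608, interval 0.556 to 0.666, adjusted Fisher p = 3e-26), and so was H3K27ac (43.6% against 55.9%, odds ratio 0.580, interval 0.533 to 0.632, adjusted p = 1.28e-36). Of the 1105 genes with H3K27me3, 864 (78.2%) had H3K4me3 (odds ratio 1.19, interval 1.03 to 1.38, adjusted Fisher p = 0.0227) and 630 (57.0%) had H3K27ac (odds ratio 1.048, interval 0.926 to 1.19, adjusted p = 0.458). H3K27me1 and H3K27me3 met on 125 genes (odds ratio 1.34, interval 1.099 to 1.63, adjusted Fisher p = 0.00504). Fisher's exact test, two-sided, was used for all 6 pairs. In the narrow lists the odds ratio of H3K4me3 with H3K27me3 was 1.51 (adjusted Fisher p = 0.00208), and that of H3K27me1 with H3K27me3 was 1.02 (adjusted p = 0.910). Counted over gene ends only, H3K4me3 and H3K27me3 had an odds ratio of 0.983, and H3K27ac and H3K27me3 had 0.850 (adjusted Fisher p = 0.0118), near the 0.856 of the narrow lists (adjusted p = 0.156).

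**Figure D3:**
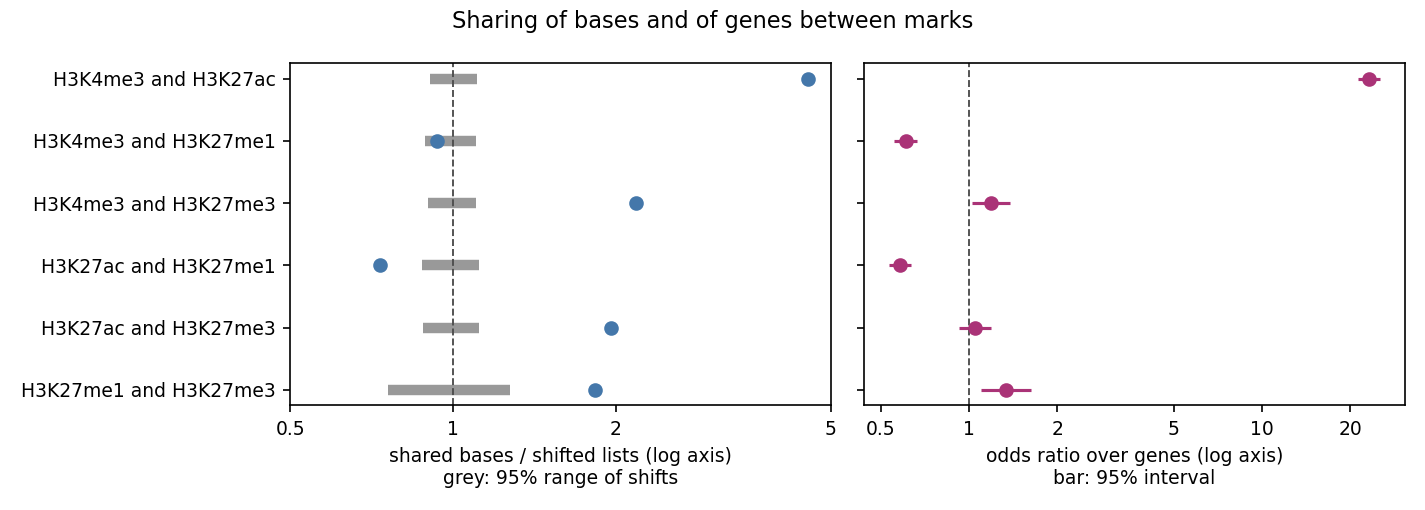
Shared bases of each pair of marks over the mean of the shifted lists (left, grey bars for the middle 95% of the shifts) and odds ratio of carrying both marks over 27444 protein-coding genes with its 95% interval (right), both on log axes. H3K4me3 with H3K27ac stands highest in both panels (4.54 and 23.2), and H3K4me3 with H3K27me1 lies below 1 in both.

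Among genes with both H3K4me3 and H3K27ac, those with a higher fold of one mark tended to have a higher fold of the other in the main lists. Across 14691 genes, Spearman's rho of the fold enrichments was 0.526 and Pearson's r of their logarithms was 0.512, each with permutation p = 1e-05, the smallest 100000 permutations can give, and adjusted p = 6e-05 over 6 relations. H3K4me3 and H3K27me1 gave rho 0.0617 (permutation p = 0.0138, adjusted p = 0.0413) and r 0.0417 (permutation p = 0.0970, adjusted p = 0.291) across 1591 genes. In the narrow lists the same pair gave rho −0.0688 across 4531 genes, so its sign depended on the list. H3K4me3 and H3K27me3 gave rho −0.0413 (adjusted permutation p = 0.450) across 864 genes, and the other 3 pairs did not pass either. In the narrow lists H3K27ac with H3K27me1 did pass, at rho −0.0578 across 2959 genes (adjusted permutation p = 0.00328). With the other peak list of both marks, rho of H3K4me3 with H3K27ac was −0.0724 and their gene odds ratio 1.08, the broad H3K27ac list marking 153 genes. Genes are not independent replicates, and in the main lists the relations with H3K27me1 and H3K27me3 rest on broad folds. H3K4me3 and H3K27ac came from input preparations 1, 2 and 3, H3K27me1 from 1 and 3, and H3K27me3 from 2 and 3. What these partly shared preparations add to the relations was not tested.

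All 16 genes of the male germline list carried both active marks. They include DUO1 (AT3G60460), the MYB factor that drives male germline development, HAP2 (AT4G11720), the gamete fusogen, and GEX2 (AT5G49150), a gamete attachment protein. The highest H3K4me3 folds of the list were 7.56 at DMP9 (AT5G39650; DAU2), 7.37 at DMP8 (AT1G09157) and 7.25 at TET12 (AT5G23030), against a median of 3.70 over all H3K4me3 peaks. DUO1 had a fold of 5.04 in a peak at chromosome 3, 22342576 to 22343690, and HAP2 had 5.07 at chromosome 4, 7063145 to 7064008. HTR10 (AT1G19890) had 4.23; its sequence is also in the reporter of the sorted line, and its −log10 q was 9.02 times the highest among H3K4me3 peaks of like fold. For H3K27ac the list passed the test (16 of 16, lower 95% bound of the odds ratio 3.04, adjusted Fisher p = 0.00174), and for H3K4me3 it did not (lower bound 1.27, adjusted p = 0.0650), though it did within gene-length strata (adjusted p = 0.0261). No member carried H3K27me1, and 2 carried H3K27me3, DMP9 and TET12 (adjusted Fisher p = 0.268).

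Most genes for Polycomb proteins and H3K27 enzymes carried the active marks, but neither mark passed the test against other genes. H3K4me3 lay on 21 of the 23 (91.3% against 75.2% of other genes, adjusted Fisher p = 0.223). H3K27ac lay on 16 (69.6% against 55.9%, adjusted Fisher p = 0.381). The demethylase genes REF6 (AT3G48430), ELF6 (AT5G04240) and JMJ13 (AT5G46910) had H3K4me3 folds of 6.46, 5.97 and 5.996, and the H3K27me1 methyltransferase genes ATXR5 (AT5G09790) and ATXR6 (AT5G24330) had 5.60 and 6.33. The H3K27me3 methyltransferase genes CLF (AT2G23380) and SWN (AT4G02020) had 3.74 and 2.67. MEA (AT1G02580) and FIS2 (AT2G35670), subunits of the Polycomb complex of the female gametophyte and endosperm, had neither active mark. H3K27me3 lay on JMJ13, with a narrow-list fold of 4.50, and on JMJ32 (AT3G45880; adjusted Fisher p = 0.396). H3K27me1 lay on FIS2 alone in the broad list and on 5 of the 23 in the narrow list (FIS2, EMF1, RING1A, VRN5 and JMJ30).

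H3K27me3 that was present in sperm lay on developmental genes far more often than on other genes, of which about 4.0% carried it. In the seed and embryo list, 9 of 18 members (50%) carried it (odds ratio 24.01, 95% interval 8.43 to 68.4, adjusted Fisher p = 4.9e-07): the regulators ABI3 (AT3G24650), ABI4 (AT2G40220) and DOG1 (AT5G45830), the cruciferin genes CRA1 (AT5G44120) and CRU3 (AT4G28520), and the albumin genes SESA1 to SESA4, which share a peak at chromosome 4, 13607818 to 13613905. The test counted SESA1 to SESA4 as separate genes despite the shared peak, so the odds ratio, interval and p of this list overstate the independent evidence. In the list of meristem homeobox and PLETHORA genes it was 10 of 27 (37.0%, odds ratio 14.1, interval 5.77 to 32.8, adjusted Fisher p = 1.26e-06), among them KNAT1 (AT4G08150), WOX9 (AT2G33880), CUC2 (AT5G53950), PLT1 (AT3G20840), ANT (AT4G37750) and SHR (AT4G37650). In the flower list it was 7 of 24 (29.2%, odds ratio 9.87, interval 3.45 to 25.1, adjusted Fisher p = 0.000553): AP1 (AT1G69120), FUL (AT5G60910), AGL24 (AT4G24540), SVP (AT2G22540), LFY (AT5G61850), SUP (AT3G23130) and SPL (AT4G27330). Epidermis, root hair and trichome genes had 4 of 16 (25%, odds ratio 7.97, interval 1.87 to 26.3, adjusted Fisher p = 0.024), which were the root hair factors RHD6, RSL2 and RSL4 and the trichome factor MYB23. Narrow-list folds were 5.74 at SHR, 4.92 at CRA1, 4.77 at ANT, 4.54 at FUL and 4.51 at ABI3. In the narrow lists the seed list (5 of 18, adjusted Fisher p = 0.00026) and the meristem list (4 of 27, adjusted p = 0.00815) passed the test, while flower (1 of 24) and epidermis (1 of 16) did not. With broad peaks of −log10 q of at least 5, only the flower call was left for H3K27me3, again by the broad-list q.

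Pollen vegetative cell genes and imprinted genes also carried H3K27me3 more often. The vegetative cell is the sister of the sperm lineage in pollen, and 4 of its 21 listed genes were marked (19.0%, odds ratio 5.62, interval 1.37 to 17.3, adjusted Fisher p = 0.0428). They were the pectin methylesterase genes VGD1 (AT2G47040) and VGDH1 (AT2G47030), each in its own peak with a narrow-list fold of 7.10, the receptor kinase gene ANX2 (AT5G28680, 4.47) and the MADS gene AGL104 (AT1G22130, 4.78), and the narrow lists called the same 4 (adjusted Fisher p = 0.00397). The narrow peaks of VGDH1 and VGD1 lie close together on chromosome 2 (19324972 to 19326067 and 19328273 to 19329832). Their −log10 q was the same, 13.1. The test counted VGD1 and VGDH1 separately, so the odds ratio, interval and p of this list may overstate the independent evidence. As markers of the other cell type of pollen, 16 of the 21 genes had H3K4me3 and 14 had H3K27ac, and neither passed the test. Among 19 imprinted genes, 4 carried H3K27me3 (21.1%, odds ratio 6.37, interval 1.54 to 20.1, adjusted Fisher p = 0.0366), which were PHE1 (AT1G65330), SUVH7 (AT1G17770), YUC10 (AT1G48910) and VIM5 (AT1G57800), and none did in the narrow list. H3K27me1 lay on 7 of the 19 imprinted genes (36.8%, odds ratio 6.07, interval 2.02 to 16.7, adjusted Fisher p = 0.00814): FWA, FIS2, YUC10, MYB3R2, JKD, VIM5 and AGL28. H3K27me1 passed for no other list in the main test, and for the flower list within gene-length strata (6 of 24, adjusted Fisher p = 0.0618, within strata 0.0418). In the narrow list it was 10 of 19 imprinted genes (adjusted Fisher p = 0.0654).

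H3K4me3 was lower on the flower list, at 11 of 24 genes (45.8%, odds ratio 0.278, interval 0.113 to 0.674, adjusted Fisher p = 0.024); AP3, PI, SEP1, SEP2, SEP4, STK and FT were among those without it, and the flowering repressor FLC (AT5G10140) had a fold of 5.51. H3K27ac was lower on the seed list, at 4 of 18 genes (22.2%, odds ratio 0.225, interval 0.0539 to 0.717, adjusted Fisher p = 0.0366), a call that ended within gene-length strata (adjusted p = 0.0905). H3K4me3 lay on all 20 DNA methylation and silencing genes (adjusted Fisher p = 0.0366) and on all 18 YUC and PIN auxin genes (adjusted p = 0.0476), but neither passed within gene-length strata (adjusted p = 0.489 and 0.271). It lay on 18 of 19 housekeeping genes, 16 of 18 histone genes and 13 of 21 photosynthesis genes, none of which passed. In the narrow list H3K27me1 lay on 11 of the 18 auxin genes (61.1%, adjusted Fisher p = 0.0243) and on no housekeeping gene (adjusted p = 0.0267), neither of which passed in the broad list, and the housekeeping call ended within gene-length strata (adjusted p = 0.0909). H3K27me3 lay on 2 DNA methylation genes (CMT3 and DDM1), on 1 histone gene (HTR6) and on no housekeeping or photosynthesis gene, and none of these lists passed. Over the 13 lists and 4 marks, 12 of 52 tests passed, 10 higher and 2 lower. Of the 48 list genes with H3K27me3, 37 also had H3K4me3, 23 had H3K27ac and 18 were in the narrow H3K27me3 list.

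**Figure D4:**
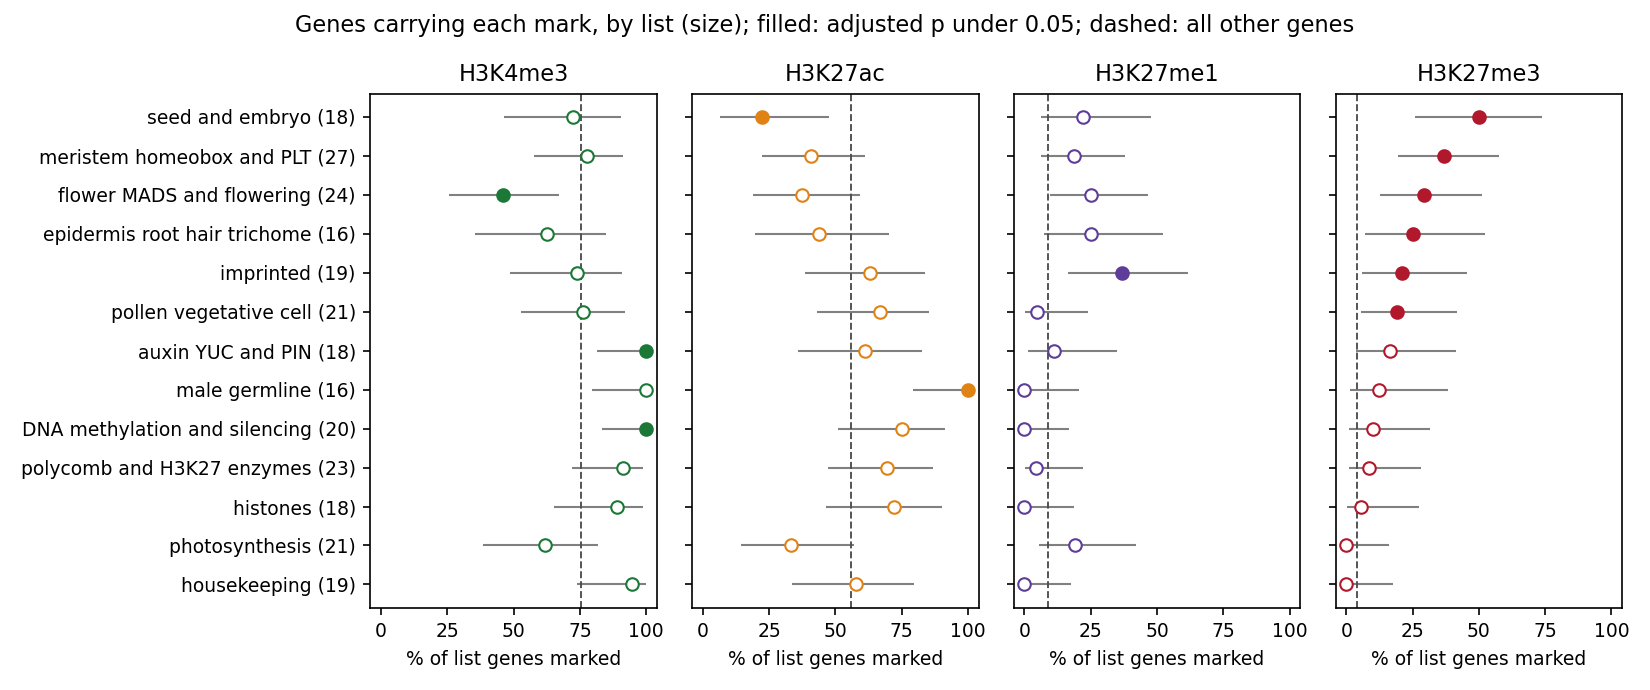
Percent of the members of each of the 13 gene lists that carry each mark, with marks as panels, 95% binomial intervals as bars, filled points for an adjusted p under 0.05 and all other genes as the dashed line. H3K27me3 stands at 50% in the seed and embryo list and at 37.0% in the meristem list.

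The strongest H3K4me3 peak was at AT5G63520 on chromosome 5, 25428372 to 25430335, with a fold of 8.45. It was followed by AT1G72880 (8.30) and AT3G24506 (8.24). The H3K27ac folds reached 2.80 at AT3G10770, 2.79 at AT4G40042 and 2.75 at the autophagy gene ATG3 (AT5G61500). In the broad H3K27me3 list the highest folds at genes were 6.19 at PAP11, 6.14 at the kinase gene MPK7 and 5.56 at SRS4. Since the broad folds did not follow the narrow ones, narrow folds, chosen after the values were seen, are given as well. In the narrow list the histone H2A gene HTA6 had the highest H3K27me3 fold, 13.9 at chromosome 5, 24115273 to 24117574. Next were AT2G07981 and AT2G08986, with 11.3 in a shared narrow peak at chromosome 2, 3614976 to 3623829. AT4G29620 (10.1), AT2G03000 (10.07) and AT4G29630 (9.92) followed. AT2G29800 had 9.01, as did the fruit patterning gene IND at chromosome 4, 42580 to 43153. The germline gene TET12 was lower, at 7.65, and highest among members of the gene lists. The widest H3K27me3 peak was 12415 bp at chromosome 2, 3614966 to 3627380, over AT2G07981 and AT2G08986. Of the next 4, the peak at chromosome 4, 7914999 to 7921497, lay over MEE57, and the 3 on chromosomes 5 and 1 lay over no protein-coding gene. H3K4me3 peaks with a −log10 q over 3 times the median of peaks of like fold lay inside the widest peak (3615038 to 3615899 and 3616515 to 3622670) and inside the next widest on chromosome 5 (11732009 to 11735930). Those inside the widest peak also lay within the narrow H3K27me3 peak of AT2G07981 and AT2G08986.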

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

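No paired analysis was possible because each peak list covers all replicates of its mark, with no values per replicate. Leaving out replicates and a replicate block were not run for the same reason, gene-start windows because the gene table has no strand, and motifs because no genome sequence was used here. Chosen after the data were seen were the window at either gene end, genes outside pericentromeres, narrow lists for all marks in the gene lists and rank correlations, and the germline list without HTR10. Of 388 alternative values, 259 were counted as kept. These stayed on their side of the threshold or, for values without a test, within the range set for them. A change of direction between values that both did not pass was counted as kept. Of the rest, 58 fell short of the threshold, 7 newly passed, 39 of those without a test moved and 25 reversed. The depth of the samples is unknown, so how much it adds to the unlike calling of the marks cannot be given. Where no reason is given, the cause was not tested.

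With the other peak list of each mark, peaks numbered 11480 (H3K4me3), 163 (H3K27ac), 13130 (H3K27me1) and 478 (H3K27me3), and genes marked were 153, 7370 and 405 for the last 3 marks. The share of peaks within 500 bp of a gene end was 58.3% for H3K4me3, 43.6% for H3K27ac and 24.4% for H3K27me1. The ratio in sequence with no annotated gene was 0.665 for H3K27me3. Overlap ratios were 0.510 for H3K4me3 with H3K27me1, 0.784 for H3K27ac with H3K27me1 and 0.798 for H3K27ac with H3K27me3. Gene odds ratios were 1.08 for H3K4me3 with H3K27ac, 1.19 for H3K4me3 with H3K27me3 (adjusted p = 0.302), 1.14 for H3K27ac with H3K27me1 and 1.02 for H3K27me1 with H3K27me3, and rho of H3K4me3 with H3K27ac was −0.0724. List tests passed in 5 cases, 3 of them for H3K27me3, against 12 and 6. No imprinted gene had H3K27me3 and no male germline gene had H3K27ac (0%), the broad H3K27ac list marking 153 genes.

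With narrow lists for all marks, the overlap ratio of H3K4me3 with H3K27me1 was 0.612 and the odds ratio of H3K27me1 with H3K27me3 was 1.02. There rho was −0.0688 for H3K4me3 with H3K27me1 and −0.0578 for H3K27ac with H3K27me1 (adjusted permutation p = 0.00328). H3K27me3 passed for 3 lists and marked 0% of imprinted genes.

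With −log10 q of at least 5, which leaves fewer peaks, 596 H3K27me1 and 81 H3K27me3 peaks stayed, on 540 and 64 genes. Ratios for H3K27me1 were 1.2 in gene interiors, 0.759 in pseudogenes and transposon genes, 0.991 with no annotated gene and 0.761 in pericentromeres. Overlap ratios were 1.26 for H3K4me3 with H3K27me1, 1.67 for H3K27ac with H3K27me3 and 4.54 for H3K27me1 with H3K27me3. Odds ratios were 1.11 for H3K4me3 with H3K27me3 and 2.46 for H3K27me1 with H3K27me3. Near gene ends lay 70.9% of H3K27ac and 37.0% of H3K27me3 peaks. List tests passed in 5 cases, 1 for H3K27me3 (flower), and 0% of the epidermis, imprinted, meristem, vegetative cell and seed lists had H3K27me3 and 0% of the imprinted list H3K27me1.

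With a fold of at least 2, again with fewer peaks, 3450 H3K27ac, 5 H3K27me1 and 237 H3K27me3 peaks stayed, on 3433, 5 and 182 genes. The 5 H3K27me1 peaks were too few (under 20) for tests. The H3K27me3 ratio was 0.572 in RNA genes, and its odds ratio with H3K4me3 was 1.29. List tests passed in 3 cases, 1 for H3K27me3, which marked 0% of the epidermis and seed lists. Broad folds did not follow narrow ones, and whether broad folds and q values belong to their coordinates is open, so changes in H3K27me1 and H3K27me3 under this setting and the former are no measure of weak or strong peaks.

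At an overlap of 1 bp the odds ratio of H3K4me3 with H3K27me3 was 1.11. Within 500 bp of either gene end it was 0.983, that of H3K27ac with H3K27me3 was 0.850 (adjusted p = 0.0118), rho of H3K4me3 with H3K27me1 was 0.0547, and list tests passed in 5 cases, 2 for H3K27me3. For that pair the rank correlation was 0.0563 with the mean fold, and the overlap ratio was 0.936 with uniform placement. The germline list without HTR10 gave 12 list calls. Gene-length strata also gave 12 but with other members: H3K4me3 on the DNA methylation and auxin lists and H3K27ac on the seed list were lost, and H3K4me3 on the male germline list (adjusted p of 0.0261), H3K27ac lower on the flower list (0.0418) and H3K27me1 higher on it (0.0418) were gained.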

Other observations

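Chosen only after the result was seen were the tests of values shared by neighbouring broad peaks, of extra HTR10 copies and of the genes activated by DUO1. Among genes named in the annotation as members of transcription factor families, 99 of 636 (15.6%) carried H3K27me3, against 3.75% of other genes (odds ratio 4.73, 95% interval 3.74 to 5.93, adjusted p = 8.37e-30 over 76 tests, Fisher's exact test). In the narrow list it was 41 genes (6.45%, odds ratio 5.01). By family, 11 of 32 zinc finger genes (34.4%), 6 of 22 TCP genes (27.3%), 16 of 71 homeobox genes (22.5%) and 18 of 133 MYB genes (13.5%) were among those that passed, while bHLH (3 of 22), GATA (4 of 30) and YABBY (1 of 4) did not pass. Cytochrome P450 genes, which are not regulators, carried H3K27me3 on 36 of 239 (15.1%, odds ratio 4.34, adjusted Fisher p = 1.78e-10), and H3K27me1 on 33 (13.8% against 8.74% of other genes, odds ratio 1.67), or 139 in the narrow list (58.2% against 26.6%). Defensin-like genes had little of either active mark: H3K4me3 lay on 17 of 121 (14.0%, odds ratio 0.0531, interval 0.0298 to 0.0892) and H3K27ac on 21 (17.4%). H3K4me3 lay on 14 of 34 RALF peptide genes (41.2%) and 15 of 30 CLE peptide genes (50%). Families were gathered by gene symbol and are only as complete as the symbols are. Gene length was not held equal in the family tests. Median gene length was 2288 bp with H3K4me3, 2332 bp with H3K27ac, 2005 bp with H3K27me1 and 1947 bp with H3K27me3, against 2078 bp for all genes. What gene length adds to the family differences, including the low shares of defensin-like, RALF and CLE genes, was not tested.

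The annotation names 9 genes as activated by DUO1, and all 9 carried H3K4me3 and H3K27ac. The hypothesis that they have more H3K4me3 than other marked genes was tested on the highest fold per gene. Their median fold stood at percentile 80.4 of marked genes, with DAN1 at 8.01, DAU2 at 7.56 and DAZ2 at 6.33. The permutation p was 0.0174, counting only random medians at least as high, so unlike the other tests it was not two-sided. The lowest were DAF1 at 4.99 and DAA1 at 4.22. DAZ1, DAZ2, DAZ3 and DAU2 were also in the male germline list. H3K27me3 lay on DAU2 in the broad list and on none of the 9 in the narrow list.

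In the broad lists of all 4 marks the fold of a peak did not follow that of the narrow peak within it, and for H3K27me3 (rho −0.0468 over 457 peaks), of the 61 broad peaks with a fold of at least 3, 23 lay on chromosome 2 from 7 to 10 Mb and 17 on chromosome 5 from 24 to 27 Mb. Averaging over wider regions was argued against by broad H3K27me3 peaks at most 1.5 times as wide as their narrow peak, where rho was −0.0207 (95% interval −0.132 to 0.0922, 293 peaks). Chromosome regions with more H3K27me3 stay open. The 21 narrow peaks that touch those 61 broad peaks had a median fold 1.046 times that of the other narrow peaks (interval 0.938 to 1.14). This cannot decide it, because a ratio near 1 restates that broad folds do not follow narrow ones. Values shared between neighbouring peaks stay open: adjacent broad H3K27me3 peaks had rho 0.406 (interval 0.357 to 0.455) and adjacent narrow peaks 0.0441 (interval −0.0437 to 0.136), but H3K4me3 has the same mismatch (rho −0.0562 over 11079 peaks) with little sharing (0.0402 broad, 0.0307 narrow), and H3K27me1 has it (rho −0.151) with some (0.183 broad, 0.0712 narrow). Values assigned to other coordinates than their own stay open too, and no biological explanation was tested.

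HTR10 had the highest −log10 q of all 22150 H3K4me3 peaks (1111, chromosome 1, 6904922 to 6905789) with a fold of 4.23, which stood at percentile 61.6. A gain of the whole region was argued against by the nearest peaks on either side, at most 1.16 times the median −log10 q of peaks of like fold. Extra copies of HTR10 sequence in the reporter line stay open: the value was 9.02 times the highest of 1984 peaks of like fold, and for H3K27ac 8.76 times the highest of 5438, but this excess is the pattern itself. In addition, 6 other H3K4me3 peaks had a −log10 q over 3 times the median of peaks of like fold, including 18.5 times at chromosome 3, 14194009 to 14195621. Copy number and input reads were not examined, and no biological explanation was tested.

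H3K27me3 and H3K4me3 shared more bases than shifted lists (ratio 2.18). A preference of both marks for genes as the whole cause was argued against by the 864 genes with both marks, where they shared 512 kb against 387 kb for placement within the gene (ratio 1.33, interval 1.29 to 1.36). Weak background signal at H3K4me3 sites was tested with the stricter narrow list. It held 340 of the 836 H3K27me3 peaks that touch H3K4me3 (40.7%) and 117 of the 587 others (19.9%, odds ratio 2.75, interval 2.14 to 3.55, p = 6.31e-17, Fisher's exact test). Peaks at H3K4me3 were thus in the stricter list more often, not less. Background in the same immunoprecipitations could enter the narrow list too, and peak width was not held equal, so background stays open. Shared input chromatin, nuclei of more than 1 kind among those sorted, and both marks on the same nucleosomes stay open, and none was tested.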
